A study of Mus musculus with 3 samples.

How the data were processed

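ATAC-seq uses the transposase Tn5 to cut and tag DNA where chromatin is open, so that stretches with many reads mark accessible regions such as promoters, enhancers and other regulatory elements. The 3 samples analysed here were made from the microdissected dentate gyrus, the part of the hippocampus that holds the granule neurons, of adult C57BL/6 mice aged 8 weeks. Per the labels' protocols, each library came from 1 individual, so the 3 samples are separate animals. All 3 carry the label E24, which the labels do not spell out, and they form 1 group of 3 replicates, numbered as in the labels. The series concerns the change of chromatin accessibility after neuronal activation. No unstimulated or other time group was analysed here, and no comparison between conditions was made.

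Per the submitters' processing notes, reads were aligned with Bowtie2 to the mouse build mm9. The deposited files are peak lists, 1 per sample, and the peak names in them are those of the caller MACS. The versions, the MACS settings, the treatment of duplicate and mitochondrial reads and any shift of read ends for the cut made by Tn5 are not given in the sources used here. Each deposited line gives the chromosome, start and end of a peak in bp, a name and a score. The deposited score has no unit in the files. Its lowest value lay at 50.0 in every list, which shows a floor applied by the authors' peak calling, and 5 peaks of each list had exactly 3100, which looks like a ceiling, although 1 peak of replicate 2 had 3213. Since such a score depends on read depth, its size was not read as accessibility. It was used to rank peaks within a list and to compare ranks. Its mean over the 3 lists was used only to order the regions held by all 3 samples. Scores of different lists, where given side by side, are not on a common scale. In regions held by all 3 samples, the median ratio of replicate 3 to replicate 2 was 0.52. The files hold no read counts, so the sequencing depth of each sample is unknown and no counting interval could be given. The number of animals limits the precision.

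The lists held no overlapping peaks, and the peak numbers in each list ran without a gap. The build is taken from the processing notes, since no chromosome lengths were provided to check it. The gene table provided is for the assembly GRCm38. Because that table is on another build, no gene was assigned to any peak. The promoter counts, gene lists, cell type marker lists and sequence motifs that had been chosen before the data were examined were therefore not computed, and regions are named by mm9 position, counted from 1.

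Peaks of different samples were joined into 1 region wherever they overlapped by at least 1 bp. For each sample, the share of its peaks overlapped in both other samples was computed. Chance overlap was estimated from 100 random placements, in which the peaks of replicates 2 and 3 were moved to random positions between the first and the last peak of their chromosome while replicate 1 stayed in place. A second set of 100 moved each of these peaks by 10 to 50 kb, to keep the local density. Score agreement was the Spearman correlation across regions held by all 3 samples, using the highest peak of each sample in a region. Regions are not independent replicates, so no p-value is given for it. Peak density on a chromosome was the number of peaks divided by the distance between its first and last peak, and relative density was this value divided by that of all autosomes of the same sample. The length between outer peaks includes any assembly gaps.

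The regions named were fixed by rule before the data were examined: the 5 highest-scoring regions held by all 3 samples, and the 3 highest-scoring regions of each sample that no other sample held. Other regions named were chosen after their values were seen, and this is said where they appear. Alternatives were a reciprocal overlap of 50%, the highest-scoring 50% of each list, an equal number of top peaks in every list, chromosomes 1 to 19 alone, and leaving out each replicate in turn. The overlap, joining, correlation and placement steps were tested on simulated lists with known sharing before use. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Errors are SD over the 3 animals.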

Results

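Accessible chromatin was mapped by ATAC-seq in the dentate gyrus of 3 adult C57BL/6 mice of the group labelled E24. The series asks how neuronal activation changes chromatin accessibility in this tissue. With 1 group, the data describe the accessible regions of these animals and how far they differed between them. Replicate 1 had 62912 peaks, replicate 2 had 68699 and replicate 3 had 48769, with a mean of 60127 ± 10253 (SD, n = 3). The peaks covered 38.3 Mb in replicate 1, 42.7 Mb in replicate 2 and 21.2 Mb in replicate 3. The median peak was 504 bp wide in replicates 1 and 2 and 353 bp wide in replicate 3. Peaks wider than 2 kb made up 0.998% of replicate 1, 1.30% of replicate 2 and 0.236% of replicate 3. Wider peaks had higher scores in every list, with a Spearman correlation across peaks of 0.780 ± 0.013 (SD, n = 3).

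The first comparison asked which accessible regions recurred in the 3 animals. Joining the lists gave 84529 regions, of which 36824 (43.6%) had a peak in all 3 animals, 19492 (23.1%) in 2 and 28213 (33.4%) in 1. The regions held by all 3 animals had a median width of 692 bp and spanned 31.0 Mb. These lengths run over all joined peaks of a region, so they are not lengths accessible in all 3 animals. The whole list of replicate 3 covered 21.2 Mb. Of the regions held by 2 animals, 14700 were those of replicates 1 and 2, 2995 those of replicates 2 and 3, and 1797 those of replicates 1 and 3. Replicate 2 alone held 13762 regions, replicate 1 alone 8988 and replicate 3 alone 5463. Between replicates 1 and 2 alone, with replicate 3 left out, 51549 regions were shared.

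**Figure D1:**
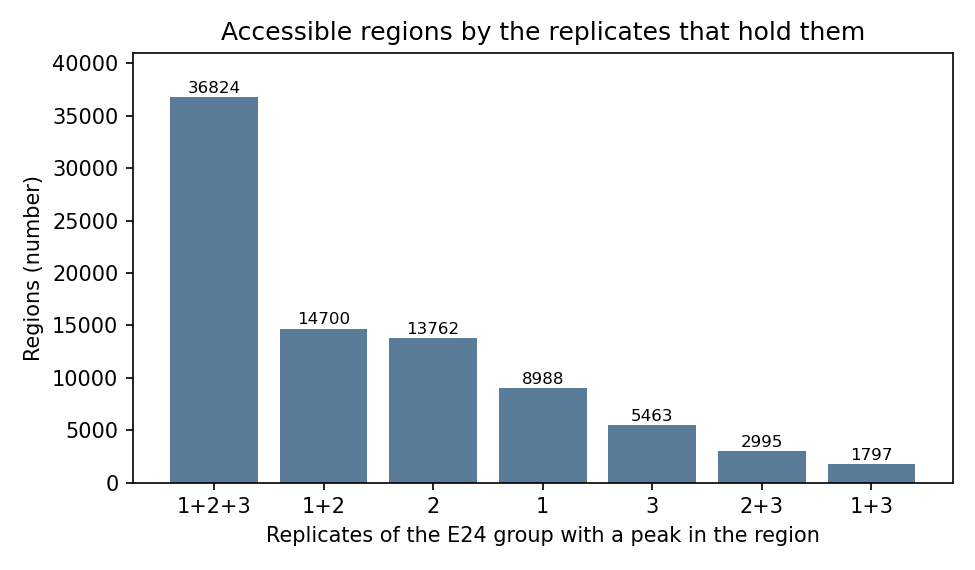
Number of joined regions (vertical axis) by the replicates of the E24 group that had a peak in them (horizontal axis). The bar of regions held by all 3 replicates stands at 36824, and the next, of regions held by replicates 1 and 2, at 14700.

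Both other animals had an overlapping peak for 58.9% of the peaks of replicate 1, 53.8% of those of replicate 2 and 78.4% of those of replicate 3, a mean of 63.68% ± 13.01 (SD, n = 3). The share was highest in the shortest list and lowest in the longest. Its SD is therefore not a spread between animals apart from list length. Of the peaks of replicate 1, 82.8% were found in replicate 2 and 61.7% in replicate 3. Of the peaks of replicate 2, 75.6% were found in replicate 1 and 58.1% in replicate 3. Of the peaks of replicate 3, 82.3% were found in replicate 1 and 84.9% in replicate 2. When the peaks of replicates 2 and 3 were placed at random on their chromosomes, a mean of 0.0776% of the peaks of replicate 1 met a peak in both, and the highest of 100 placements gave 0.103%. Moving these peaks by only 10 to 50 kb, an alternative chosen after seeing the data, gave a mean of 0.226% and a highest value of 0.273%. The observed 58.9% therefore lay far above chance overlap under both placements.

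Sharing was more frequent among high-scoring peaks in every animal. In the highest-scoring 10% of each list, 99.97% of the peaks of replicate 1, 99.99% of those of replicate 2 and 99.88% of those of replicate 3 overlapped a peak in both other animals. In the lowest-scoring 10%, the shares were 14.0%, 9.23% and 41.6%. Regions held by all 3 animals had a median score of 207 in replicate 1, against 63.2 for the regions held by replicate 1 alone. In replicate 2 these medians were 255 and 67.0, and in replicate 3 they were 124 and 59.0, close to the floor of 50. Within the regions held by all 3 animals, the Spearman correlation of scores across regions was 0.88 between replicates 1 and 2, 0.79 between replicates 1 and 3, and 0.78 between replicates 2 and 3.

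**Figure D2:**
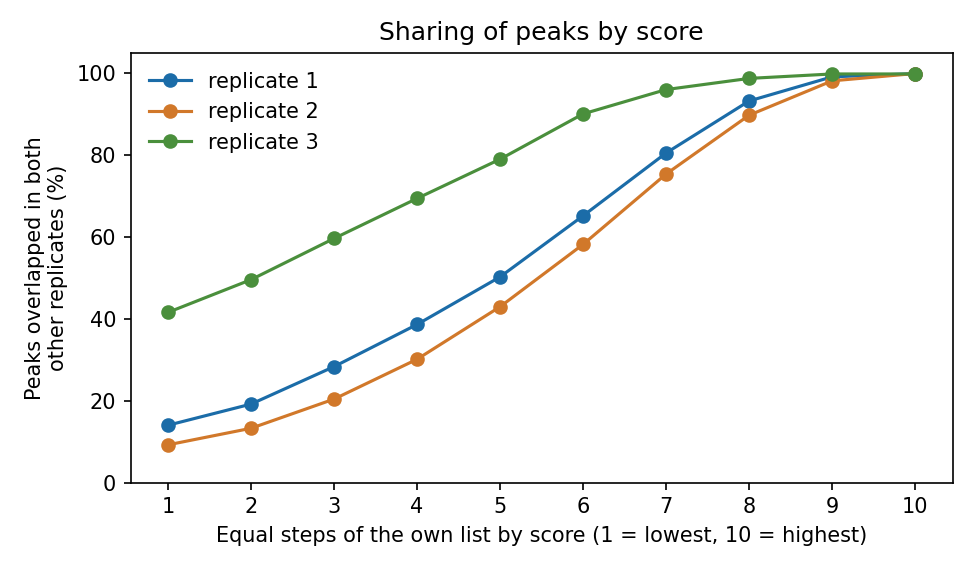
Percent of a replicate's peaks overlapped in both other replicates (vertical axis) in 10 equal steps of its own list by score (horizontal axis, 1 lowest and 10 highest), with 1 line per replicate. In the lowest step, replicate 3 stands at 41.6% and replicates 1 and 2 at 14.0% and 9.23%, and all 3 lines end between 99.88% and 99.99%.

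The regions held by all 3 animals were ranked by their mean score. In every list, exactly 5 peaks had a score of 3100, and these lay in 5 common regions, which therefore cannot be ranked among themselves. A value shared exactly by these peaks looks like a ceiling of the score, so their order relative to the largest number in the lists, 3213 at a peak of replicate 2 on chromosome 4, is not known. The region of that peak, from 118219603 to 118221535, scored 2872 in replicate 1 and 1217 in replicate 3, and is named after its values were seen. The region on chromosome 1 from 24618164 to 24623092 was 4929 bp long, and that on chromosome 2 from 22442587 to 22446263 was 3677 bp long. A second region on chromosome 2, from 98506179 to 98507576, was 1398 bp long. The other two were narrower: chromosome 9 from 35112573 to 35113353 (781 bp) and chromosome 12 from 98299575 to 98300171 (597 bp). Whether these positions lie in genes or in repeated sequence was not determined here, since no mm9 annotation was used.

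The strongest regions held by a single animal had far lower scores, except 1 region of replicate 3. For replicate 1 they lay on chromosome 3 from 50645465 to 50646118 (score 229), on chromosome 4 from 13335365 to 13335889 (score 228) and on chromosome 15 from 34895617 to 34895978 (score 227). For replicate 2 they lay on chromosome 5 from 149770526 to 149771532 (score 321), on chromosome 10 from 71295439 to 71295873 (score 299) and on chromosome 12 from 85379293 to 85380088 (score 283). For replicate 3 the strongest was a 5513 bp peak on chromosome 9 from 2999958 to 3005470, with a score of 1635. Whether this peak lies in repeated sequence or at an assembly gap was not examined, so it is not shown to be open chromatin particular to this animal. The next both lay on chromosome 6, from 47634684 to 47636708 (score 458) and from 47712172 to 47714611 (score 394).

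These chromosome 6 peaks belonged to a stretch that was called in replicate 3 alone, which was singled out after its values were seen. Between 47600577 and 47718717, a span of 118 kb, replicate 3 had 14 peaks and replicates 1 and 2 had none. The 14 peaks were 900 to 2910 bp wide, with a median of 2112 bp, and had scores from 66.5 to 458. They lay in clusters of 8 and 6, whose facing peak starts were 54436 bp apart. Together they covered 24.01% of the span, against 0.919% of chromosome 6 as a whole in the same animal. On both sides of the stretch, the 3 animals shared peaks, such as the one from 47727925 to 47728749 in replicate 3, which scored 543 there, 967 in replicate 1 and 1155 in replicate 2. The peak nearest after the stretch, from 47721695 to 47723221 in replicate 3 (score 454), was also called in replicate 1 (score 589). Replicate 2 had no peak there. Among all 100 kb windows with peaks of 1 animal only, no window of replicate 1 held more than 4 peaks and none of replicate 2 more than 5, while the window of replicate 3 in this stretch held 10.

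**Figure D3:**
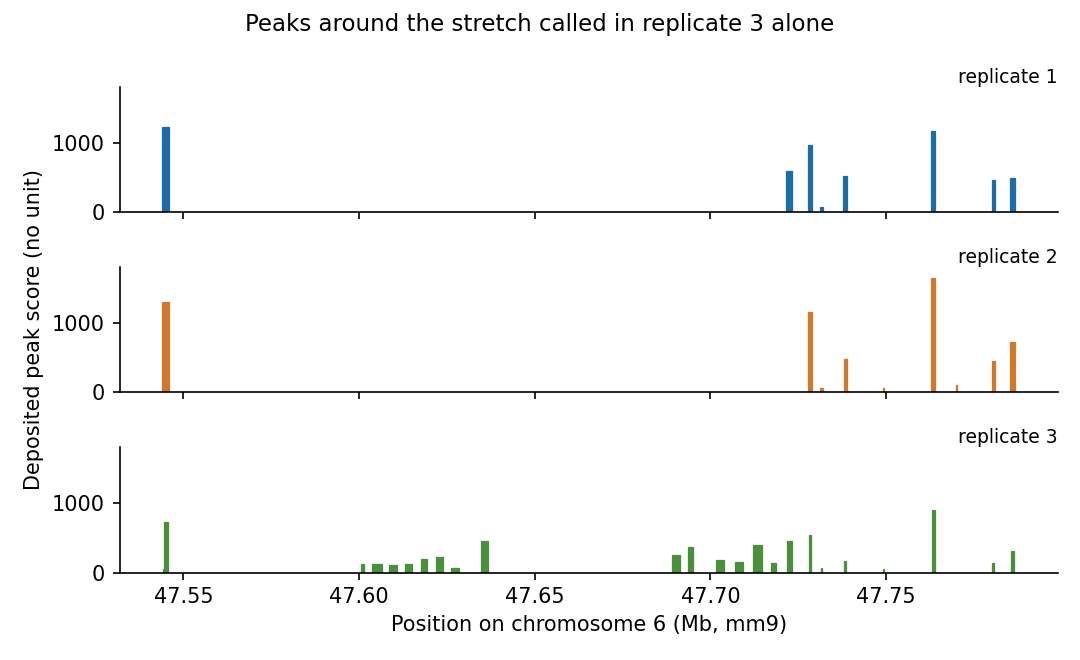
Peaks on chromosome 6 (horizontal axis, Mb, mm9) in each replicate, drawn to scale with the deposited score as height (vertical axis, no unit). Replicate 3 has 14 peaks between 47600577 and 47718717 where replicates 1 and 2 have none.

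Peaks were spread unequally over the chromosomes, in nearly the same way in each animal. Chromosome 18 had the highest density of the autosomes, 1.33 ± 0.05 times that of all autosomes together (SD, n = 3), followed by chromosome 10 at 1.26 ± 0.03 and chromosome 15 at 1.18 ± 0.01. In the highest-scoring 10% of peaks, chromosomes 18 and 10 stood at 1.42 ± 0.13 and 1.37 ± 0.05 and chromosome 13 at 1.36 ± 0.08, while chromosome 15 stood at 1.02 ± 0.02. Over all peaks, chromosome 7 had the lowest density, 0.53 ± 0.04 (0.46 ± 0.08 in the highest-scoring 10%), followed by chromosome 9 at 0.78 ± 0.02 and chromosome 17 at 0.80 ± 0.01. In peaks per Mb, chromosome 18 had 32.7, 35.7 and 27.1 in replicates 1, 2 and 3, and chromosome 7 had 13.1, 15.8 and 9.49. The difference between these chromosomes was larger than the spread between animals in each of the 3, at a ratio of 2.54 ± 0.30 (SD, n = 3). The X chromosome stood at 0.55 ± 0.02 of the autosomal density, within the spread of chromosome 7. All 3 lists held peaks on the Y chromosome, 55 in replicate 1, 63 in replicate 2 and 40 in replicate 3, and 25 Y regions were held by all 3.

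**Figure D4:**
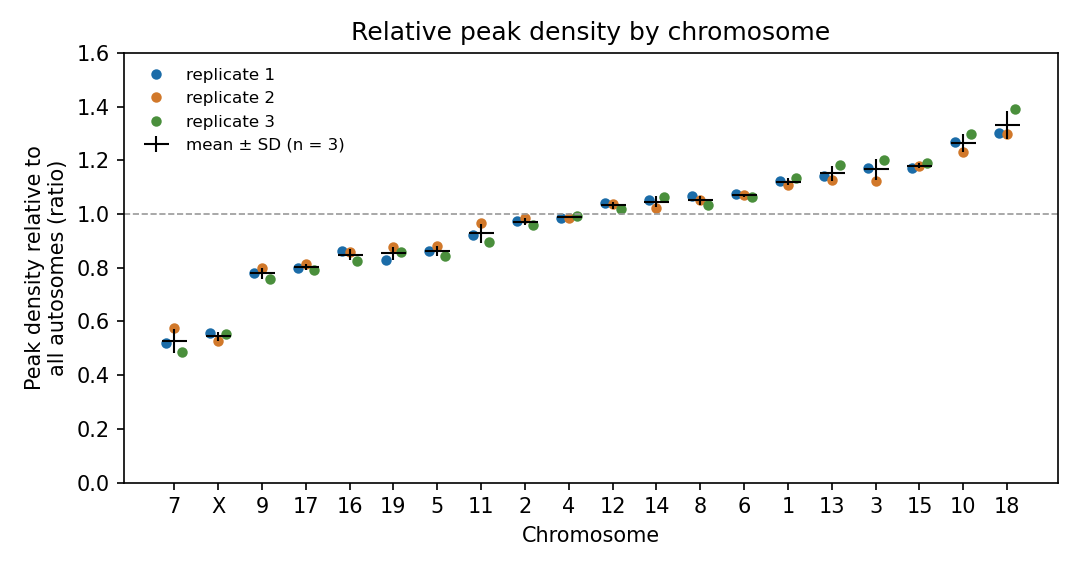
Peak density of each autosome and of the X chromosome relative to all autosomes of the same replicate (vertical axis, ratio), with chromosomes ordered by their mean. Points are replicates, black marks are the mean ± SD of 3, and the means run from 0.53 on chromosome 7 to 1.33 on chromosome 18.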

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

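Of 35 alternative values for 11 results, 25 were counted as unmoved. The bound was the spread between replicates, or a factor of 1.5 for the count of regions. For the share of peaks found in both other samples, that spread includes the effect of list length, so the bound was loose. A score correlation of a pair has no spread between replicates, so the bound does not apply to it. In the highest-scoring 50%, these correlations were 0.89, 0.81 and 0.79, against 0.88, 0.79 and 0.78 over all peaks. The count of 25 is therefore not a measure of robustness. Leaving 1 replicate out of a mean of 3 cannot move that mean by more than its SD. For the number of peaks and the densities of chromosomes 7 and 18, these alternatives were therefore bound to count as unmoved and lend no support. Taking the highest-scoring 50% of each list set the mean number of peaks to 30063 by construction, lowered the regions held by all 3 samples to 20221 and raised the relative density of chromosome 18 to 1.39. In the highest-scoring 10%, relative density rose to 1.42 on chromosome 18, 1.37 on chromosome 10 and 1.36 on chromosome 13, and fell to 1.02 on chromosome 15 and 0.46 on chromosome 7. Asking for 50% overlap of both peaks lowered the mean share of peaks found in both other samples to 46.0%. A stricter rule can only lower this share, and what set the size of the fall was not tested. Leaving out 1 replicate gave a share found in the remaining sample of 71.5% to 79.2%. The highest value was the one without replicate 3, and fewer samples to match raise this share by construction. The alternatives for chromosome density and those leaving out a replicate from the number of peaks were added after seeing the data. The alternatives intended for promoters, gene lists and motifs were not run, because no annotation or genome of the build mm9 was used. Read depth is unknown, so a region missing from a list is not shown to be closed in that animal. No paired analysis was possible because there is 1 group.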

Other observations

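The tests in this part were chosen after the patterns were seen. Only for the ratio of chromosomes 18 and 7 over windows that held a peak was the bound written before the value was computed, and that pair had already been picked as the extremes. Regions held by all 3 animals lay closer together than at random positions between the first and the last peak of their chromosome. Their median distance was 36.0 kb, against a mean of 46.6 kb over 100 random placements, whose range was 45.9 to 47.3 kb. Distances under 10 kb differed less, at 15.7% against a mean of 14.0% and a highest value of 14.4%. Random positions were not kept out of stretches where no animal had a peak, such as those named below. Neither these distances nor the fullest windows therefore test local clustering apart from such stretches. The fullest 1 Mb windows were on chromosome 13, from 23 to 24 Mb with 48 such regions and from 21 to 22 Mb with 45, while the fullest window of any random placement held 39. In the first of these windows, replicates 1, 2 and 3 had 60, 61 and 61 peaks, although replicate 3 had the fewest peaks over the genome. In the window of chromosome 10 from 80 to 81 Mb, with 42 regions held by all 3, they had 54, 65 and 48. At the other end, no animal had a peak on chromosome 7 from 39330525 to 46480956 (7.15 Mb) or on the X chromosome from 23401070 to 30515565 (7.11 Mb). Assembly gaps and repeats in these stretches were not examined.

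Replicate 3 had the fewest and narrowest peaks. Among regions held by replicates 1 and 2, replicate 3 also had a peak in 100% of the highest-scoring 10% and in 27.8% of the lowest, a difference of 72.2 points. The corresponding difference was 36.5 points for replicate 1 and 23.8 for replicate 2, each among regions held by the other 2 animals. Those regions had to be in the list of replicate 3, the shortest, so the differences come from unlike sets of regions. Low-scoring regions were thus the ones most often missing in any animal. These differences cannot tell whether weaker signal or fewer reads lowered the number of peaks in replicate 3. Overlap cannot tell whether the strong regions of replicate 3 were also strong in the others, since a peak of any score counted. A large set of strong regions called in replicate 3 alone is argued against. Of its highest-scoring 10% of peaks, 0.0820% (4 peaks) was found in neither other animal. Those 4 were the chromosome 9 peak named above and the peaks of the chromosome 6 stretch with scores of 458, 394 and 371. Replicates 1 and 2 each had 0 such peaks. Depth, tissue handling and the animal itself stay open as sources of the lower number, as the files hold no read counts.

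The 14 neighbouring regions of replicate 3 alone on chromosome 6 are a hypothesis of local excess in 1 library. Shuffling the sample patterns over all regions gave a run as long in 0 of 1000 permutations, with a longest run of 6, which argues against a chance run of regions held by replicate 3 alone. The median peak of the run was wider than 99.8% of all peaks of replicate 3. Of the 13 distances between neighbouring peak starts, 12 were 2957 to 8563 bp, with a median of 4877.5 bp. The other distance was 54436 bp, so the run is made of clusters of 8 and 6 peaks with a long empty part between them. Extra copies of the segment among the reads of replicate 3 may give such wide, close peaks within the clusters, but so might accessibility of these parts in this animal. These explanations cannot be told apart without read coverage or the sequence. Repeated sequence and assembly gaps in the stretch were not examined.

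The unequal density of autosomes may be technical or biological. Over the 19 autosomes, relative density had an SD, less counting error, of 0.19 ± 0.02 (SD over replicates, n = 3). In the highest-scoring 10% of each list it was 0.23 ± 0.05, so peaks near the lowest reported score did not set the spread as a whole. Chromosome 15 stood at 1.18 over all peaks and 1.02 in the highest-scoring 10%, and the cause was not tested. Over 1 Mb windows that held a peak, the SD over autosomes was 0.18 ± 0.02, which argues against whole empty windows as what set the spread. Windows with few peaks were kept, so shorter or sparse stretches were not tested. For chromosomes 18 and 7, chosen as the extremes, the ratio was 2.54 over all peaks, 3.18 ± 0.84 in the highest-scoring 10% and 2.29 ± 0.27 over windows with a peak (SD, n = 3). Base composition, mappability and gene content were not tested, and no biological explanation was tested.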
